A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

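RNA from 6 shaken cultures of Saccharomyces cerevisiae, 3 of a flor strain and 3 of a wine strain, was labelled with Cy3 and hybridised to 1-colour Agilent yeast arrays, per the labels' protocols. The values used are the authors' deposited log2 intensities, 1 per probe and array, for 6227 probes. That the scale is log2 was read from the values (5.29 to 15.88, the range of a 16-bit scanner signal), and the columns have nearly one distribution, with lower quartiles of 7.11 or 7.12, medians of 8.33 to 8.35 and upper quartiles of 9.68 or 9.69, so they had been normalized between arrays before deposit. The submitters' processing notes name R 2.14.2 and limma. The background correction, the normalization method, the treatment of replicate spots and any filter are not given in the sources used here, and neither detection calls nor scanner files were used. Normalization to one distribution removes any difference in total RNA between the strains, so every change is relative to the other genes. At the low end, background limits how far a fold can be read, and no probe could be called absent. A probe designed on another strain's sequence can also bind less well where a strain differs, which these values do not show.

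Probes were named through the platform annotation supplied with the series, which can be old. Of the 6227 probes, 4061 had 1 gene symbol, 0 had several and 2166 had none and are left unnamed. Through the gene table of the R64 assembly (S288C), 125 symbols were updated, after which 4053 matched and 8 were kept as annotated. The R64 table was used for names, for the order of genes along chromosomes and for coding lengths, and no coordinates are given because the array's own build is not stated. FDH2 had 2 probes, which were averaged, so that 6226 features were tested, 4060 named genes and 2166 unnamed probes. No filter on intensity was applied.

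The design text compares 2 strains with 3 biological replicates each. A model with the strain means only was fitted to all 6 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, and the contrast was flor minus wine. Adjusted p-values are those of Benjamini and Hochberg over all 6226 features, with a threshold of 0.05. Folds are powers of 2 of the log2 changes, with 95% intervals from the moderated standard errors. A rank test of 3 arrays against 3 cannot go below an exact p of 0.10, so none was used for single genes. Groups of genes were tested with camera on the same fit, with the preset correlation of 0.01 and adjustment over the 42 lists, and with an estimated correlation and fry as alternatives. The 42 lists covered cell type and mating, MAP kinase and PKA signalling, adhesins and the cell wall, carbon, nitrogen, vitamin, lipid and metal metabolism, stress, ribosomes, the cell cycle, meiosis, laboratory marker genes and reference genes missing from many strains. Chromosomes were tested with camera, and genes at chromosome ends with Fisher's exact test.

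The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names the 10 largest increases and decreases among genes that passed and whose strains did not overlap, all a-specific and alpha-specific genes, FLO11, FLO8, TEC1, STE12, RGA2, SFL1 and HO, and up to 4 members of each other list with the largest changes past the threshold. Further members named to complete counts of 5 or fewer, PAU23, and CAT8 as the member of its list that did not pass, were chosen after their values were seen. The alternatives were quantile normalization, centring on the median or the 75th percentile, removal of the dimmest 25% or 50% of features, an intensity trend with robust eBayes, array weights, slide as a block, 1 slide alone, the replicate number as a block, the omission of each array, 3 other treatments of probe rows, an adjusted p under 0.01, and a test against a log2 change of 0.5. Removal of a length trend was added after seeing the data. It was a loess, on log2 coding length (span 0.5), of each array's deviations from the mean over the arrays of both strains. Such deviations include the strain difference, so the part of that difference that follows coding length was removed too. The arrays came from 2 slides, per the labels. Slide 1 held flor replicate 3 and wine replicate 2, and slide 2 held the other 4 arrays. Replicate 2 of each strain carries a technical replicate number of 2 in its label, and no partner array was analysed here.

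The test was checked on simulated data for the flor and wine comparison with 6226 genes, of which 50 were changed at each size. It recovered 12% of genes with a log2 change of 0.25, 90% at 0.5, 100% at 1 and 100% at 2. Of 154 calls, 3 (1.9%) were of unchanged genes and 0 had the wrong sign. The real data gave 2746 calls, so the share of changed genes, on which the cut-off depends, may be far larger there. No simulated array deviated across many genes together, as flor replicate 1 did. The recovered and false shares therefore need not hold for the real comparison. A list shifted on purpose passed, and 0 of 39 unshifted lists did. The simulated genes varied independently of each other, so this check does not cover lists whose members vary together. The estimated correlation reached 0.898 in the real lists (PAU genes).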

Results

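Transcript levels were measured in 6 cultures of budding yeast, 3 of a haploid flor strain and 3 of a haploid wine strain. Flor yeasts grow as a floating film (velum) on fortified wines after fermentation, whereas wine yeasts carry out the fermentation itself. The flor strain, P3_Kan in the sample titles, is of mating type alpha according to the labels, and the wine strain, K1_Kan, is of mating type a, so that mating type and strain differ together. Both titles carry Kan, which the labels explain for the flor strain as a KanMX drug-resistance cassette and do not explain for the wine strain. Both were shaken at 28 °C in a synthetic medium resembling wine and collected at an optical density of 1 at 600 nm, and the labels state that no velum forms under shaking. The title of the series concerns MAP kinase signalling in flor yeast, and the comparison asks which genes differ between the strains when both grow in suspension. Each array gave a log2 intensity for 6227 probes, with medians between 8.33 and 8.35 and values between 5.29 and 15.88. Pearson correlations across probes were 0.9971 to 0.9975 among the wine arrays, 0.9877 to 0.9971 among the flor arrays and 0.9367 to 0.9503 between strains. The lowest values among the flor arrays belonged to replicate 1, which correlated at 0.9877 with replicate 2 and at 0.9903 with replicate 3. The first principal component, with 87.4% of the variance, separated the strains, and the second, with 8.1%, set flor replicate 1 (13.9) apart from flor replicates 2 and 3 (−9.4 and −5.9). Precision is limited by the number of arrays, 3 per strain, and the p-values measure the spread between these cultures, which the labels call biological replicates without saying more of their origin.

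The flor strain expressed the adhesin gene FLO11, the hexose transporter genes HXT3, HXT4 and HXT2 and the alpha-factor genes far above the wine strain, and it expressed ADH2, CIT3, the formate dehydrogenase genes and a-factor genes far below it. HXT3 was 81.1-fold higher in the flor strain (95% interval 69.3 to 94.9), at a log2 intensity of 15.06 ± 0.18 against 8.72 ± 0.04 (SD, n = 3 per strain, as for every ± below). FLO11, which encodes the cell surface adhesin of biofilms and pseudohyphae, was 52.8-fold higher (37.1 to 75.1), at 13.08 ± 0.54 against 7.36 ± 0.07. ADH2, the alcohol dehydrogenase that oxidises ethanol, was 26.5-fold lower (21.2 to 33.0), at 8.25 ± 0.29 against 12.98 ± 0.13. Of 6226 features tested (4060 named genes and 2166 unnamed probes), 2746 (44.1%) differed at a limma adjusted p under 0.05, of which 1276 were higher and 1470 lower in the flor strain. A log2 change of at least 1 was found for 399 of them, 241 higher and 158 lower, and the median size of a change past the threshold was 0.49. The 3 values of one strain lay entirely above those of the other in 3495 features (56.1%), where chance gives 10%. The counts were 1200 higher and 1378 lower with slide as a block. On the slide with 2 arrays per strain, 1424 features passed, and 1419 of these (99.6%) changed in the same direction on the slide with 1 array per strain.

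The 10 largest increases among named genes were those of MF(ALPHA)1 (log2 change 7.17), HXT3 (6.34), HXT4 (5.83), FLO11 (5.72), MF(ALPHA)2 (5.33), SOR1 (5.16), SEO1 (5.15), HXT2 (4.82), STE3 (4.66) and PRM7 (4.36). SOR1 encodes sorbitol dehydrogenase and has a near-identical copy, SOR2, and the HXT genes form a family of similar sequence, so their probe assignments are uncertain. SEO1 encodes a permease of the allantoate family. The 10 largest decreases were those of FDH1 (−5.63), HMRA1 (−5.62), FDH2 (−5.47), CIT3 (−5.33), STE2 (−4.79), ADH2 (−4.73), MFA2 (−4.29), BAP3 (−4.03), PDH1 (−4.01) and MFA1 (−3.61). FDH1 and FDH2 are near-identical formate dehydrogenase genes whose signals cannot be separated with certainty, and the second is annotated as a pseudogene in the R64 reference. CIT3 encodes a mitochondrial citrate and methylcitrate synthase, PDH1 a protein of propionate use and BAP3 a permease of branched-chain and other amino acids. SE was 0.22 for FLO11 and at most 0.14 for the other 19 genes, and their adjusted p-values ran from 8e-11 for MF(ALPHA)1 to 2.1e-07 for FLO11. All 20 kept their calls in every alternative setting that was run.

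**Figure D1:**
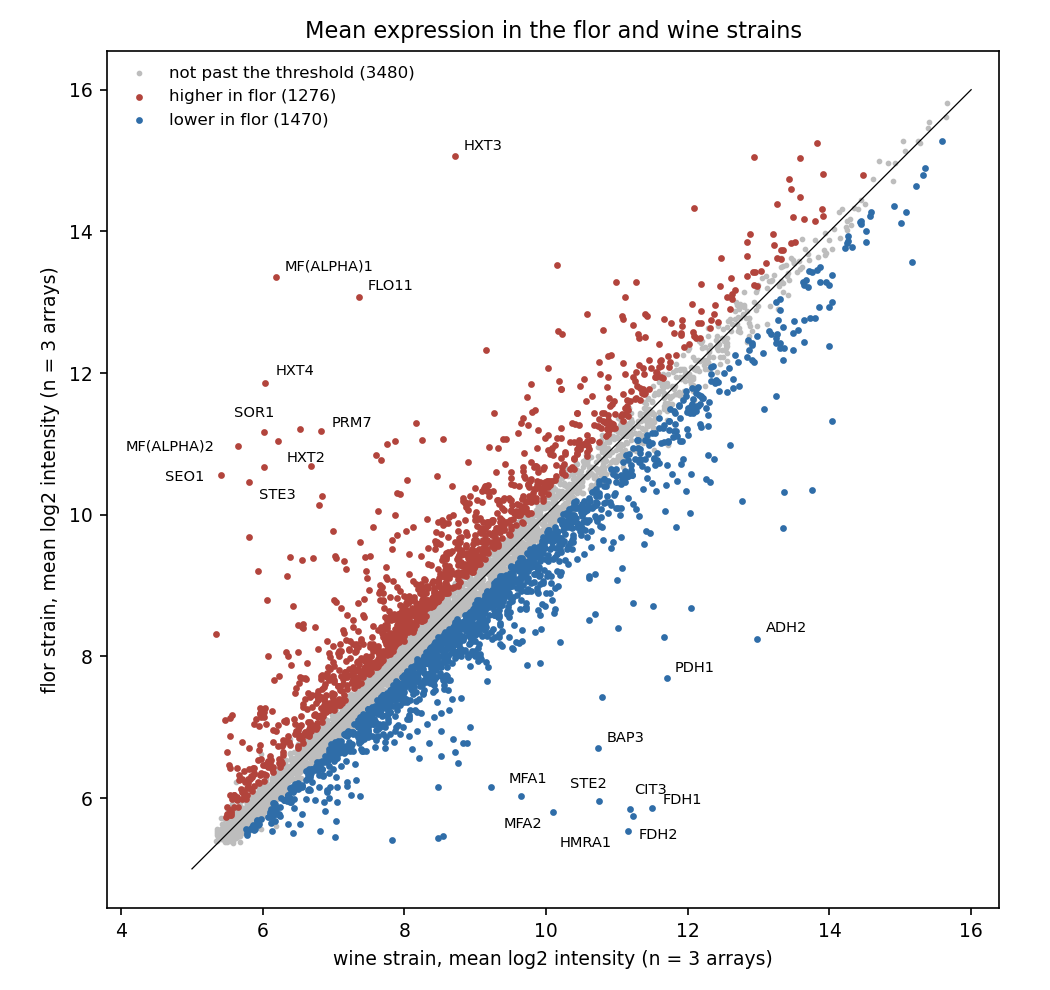
Mean log2 intensity of each feature in the wine strain (x axis) and the flor strain (y axis), n = 3 arrays each, with the 1276 features higher in the flor strain in red, the 1470 lower in blue and the rest in grey; the line marks equal means. The labels mark the 10 largest increases and 10 largest decreases among named genes, from 7.17 for MF(ALPHA)1 to −5.63 for FDH1, and unnamed probes carry no label.

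The genes that mark mating type followed the labels. All 7 measured a-specific genes, which encode a-factor, its exporter, the alpha-factor receptor and other products of a cells, were lower in the flor strain, and all 4 alpha-specific genes were higher. The a-specific changes were −4.79 for STE2, −4.29 for MFA2, −3.61 for MFA1, −3.36 for STE6, −3.07 for BAR1, −1.37 for AGA2 and −1.20 for ASG7. Of the alpha-specific genes, MF(ALPHA)1 was 144-fold (128 to 162), MF(ALPHA)2 40.2-fold, STE3 25.3-fold and SAG1 10.8-fold higher in the flor strain. The a-specific list had a median of −3.36 (camera adjusted p = 4.1e-08; medians −3.34 on slide 1 and −3.37 on slide 2) and the alpha-specific list a median of 4.99 (adjusted p = 1.5e-06; slides 5.10 and 4.94). Neither passed with an estimated correlation (adjusted p = 0.32 with an estimated correlation for each). In the strain that does not use them, these 11 genes gave log2 intensities of 5.65 to 7.43 (median 6.03, with 5 of the genes under 6). Where the lower value is near the bottom of the measured range, the fold can understate the change. Among the 6 mating-type cassette probes, HMRA1 was lower and HMLALPHA1 (3.24), MATALPHA1 (3.10), HMLALPHA2 (1.40), HMRA2 (1.37) and MATALPHA2 (1.33) were higher in the flor strain (median 1.38, slides 1.40 and 1.38, adjusted p = 0.0055; 0.47 as adjusted p with an estimated correlation). The cassettes share sequence, so these probes do not identify the locus expressed. HO, the mating-type switching endonuclease, was at 5.43 ± 0.11 and 5.49 ± 0.15 in the flor and wine strains (log2 change −0.07, adjusted p = 0.63). Among 18 markers of diploidy and meiosis, only NDT80 (0.62) and REC8 (0.56) were higher and none was lower (median 0.01, camera adjusted p = 0.75; 1 lower without flor replicate 1).

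Along the signalling routes to FLO11, single genes passed the test while no list did by camera. The transcription factor genes TEC1 (−0.19, adjusted p = 0.21), STE12 (−0.17, adjusted p = 0.097) and FLO8 (−0.16, adjusted p = 0.17) and the repressor gene SFL1 (−0.13, adjusted p = 0.44) did not pass the test, with 95% intervals of the fold of 0.954 to 1.37, 1.00 to 1.26, 0.976 to 1.27 and 0.895 to 1.34 towards a lower level in the flor strain. SFL1 lay near the bottom of the measured range in both strains (5.80 ± 0.14 in flor, 5.93 ± 0.23 in wine), so its interval may not bound a change in expression. RGA2, a GTPase-activating protein of Cdc42 and so a brake on the filamentation MAP kinase route, was 1.30-fold lower (1.14 to 1.47) in the flor strain, at 7.57 ± 0.10 against 7.95 ± 0.05 (adjusted p = 0.0058), but not on slide 2 alone (adjusted p = 0.10) or once the length trend described below was removed (adjusted p = 0.062). In the filamentous growth MAPK list, 4 of 22 genes were higher and 7 lower (median −0.08, camera adjusted p = 0.66). The mucin sensor MSB2 was lower by a log2 change of −0.91, BEM1 by −0.48 and the kinase STE20 by −0.42, and PGU1 (0.38), STE50 (0.34), CDC42 (0.34) and DIG2 (0.25) were higher. PGU1 lay near the bottom of the measured range in both strains, at 5.87 ± 0.05 in the flor strain and 5.49 ± 0.05 in the wine strain. BEM1 and DIG2 lost their calls without wine replicate 1 (adjusted p = 0.069 and 0.076), 2 (0.079 and 0.057) or 3 (0.052 and 0.067), and STE50 and CDC42 without wine replicate 2 (0.054 and 0.060). With wine replicate 2 left out, 1 gene of this list was higher and 4 lower, and 4 were lower without wine replicate 1 or 3. The haploid-specific and pheromone pathway core list had 4 of 18 genes higher, MSG5 (0.57), GPA1 (0.49), STE50 and DIG2, and 3 lower, RME1 (−1.01), STE20 and DIG1 (−0.35), with a median of 0.04 (adjusted p = 0.79). DIG1 did not pass without flor replicate 3 or wine replicate 1, 2 or 3 (adjusted p = 0.057, 0.067, 0.051 and 0.073), and without wine replicate 2 only 2 core genes were higher. Of 20 pheromone-induced targets, 8 were higher, PRM2 most (2.74), and 7 lower, MFA2, MFA1 and ASG7 most. The median was −0.02 (camera adjusted p = 0.88, but 0.0034 by fry). MFA2, MFA1 and ASG7 are also a-specific genes, so this list cannot separate mating type from pheromone signalling. In the RAS and cAMP-PKA list, IRA2 (0.46), PDE1 (0.44) and TPK2 (0.26) were higher and RAS2 (−1.18) and SOK2 (−0.30) lower among 18 genes (median −0.14, adjusted p = 0.63). The counts adjusted over the list alone were 2 higher and 1 lower. SOK2 did not pass with slide as a block (adjusted p = 0.052) or without flor replicate 3 or wine replicate 2 or 3 (0.11, 0.13 and 0.10), which left 1 gene lower, nor did TPK2 without these arrays or wine replicate 1 (0.063 to 0.13).

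Of 20 transcription factors acting on FLO11, HMS1 (1.86, 3.64-fold), MGA1 (1.29), RIM101 (0.52) and WAR1 (0.37) were higher and YAP6 (−0.87), ASH1 (−0.62), HAA1 (−0.35) and SOK2 lower in the flor strain. ASH1 and SOK2 did not pass without wine replicate 2 (adjusted p = 0.057 and 0.13), which left 2 lower, and SOK2 also failed without flor replicate 3 or wine replicate 3 (0.11 and 0.10) and with slide as a block (0.052). The median was −0.12 and the mean 0.04 (camera adjusted p = 0.87, towards lower). Among 9 flocculins and adhesins, FLO1 (1.64), FLO5 (1.48) and FLO9 (0.80) were higher besides FLO11, and FIG2 (−0.34) was lower. FLO1, FLO5 and FLO9 are near-identical over long stretches, and their probes may not separate them. The adhesin list had a median of 0.05 and an adjusted p of 0.080, and it passed without flor replicate 1 (adjusted p = 0.044). Of 29 cell wall proteins, 7 were higher, with PIR3 (1.62) first, and 15 lower, with the mannoprotein CWP1 (−3.04, 8.24-fold) and the daughter-cell separation proteins DSE2 (−2.05) and DSE4 (−2.01) first. That list had a median of −0.56 (adjusted p = 0.081), and it passed without flor replicate 2 (adjusted p = 0.026), while 11 were higher without flor replicate 1. In the cell wall integrity MAPK list of 22 genes, PST1 (1.00), MKK2 (0.76) and RLM1 (0.47) were higher and WSC3 (−0.90), MID2 (−0.52), SWI6 (−0.38), ROM2 (−0.37) and BCK1 (−0.25) lower (median −0.06, adjusted p = 0.88). Without flor replicate 1, 7 were higher. Without wine replicate 2, SWI6, ROM2 and BCK1 lost their calls (adjusted p = 0.068, 0.063 and 0.12), which left 2 lower, and without wine replicate 3 ROM2 and BCK1 did (0.067 and 0.088), which left 3. BCK1 did not pass without flor replicate 3 or wine replicate 1 either (0.060 and 0.052). The HOG pathway and osmotic target list had 7 of 21 genes higher, with GRE1 (1.14) and GPP2 (0.95) first, and 7 lower, with the glycerol symporter STL1 (−3.37, 10.3-fold) and MSB2 first. Its median was 0.11 and its mean −0.07 (adjusted p = 0.87, towards higher), and with p adjusted over the list alone 7 were higher and 8 lower.

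**Figure D2:**
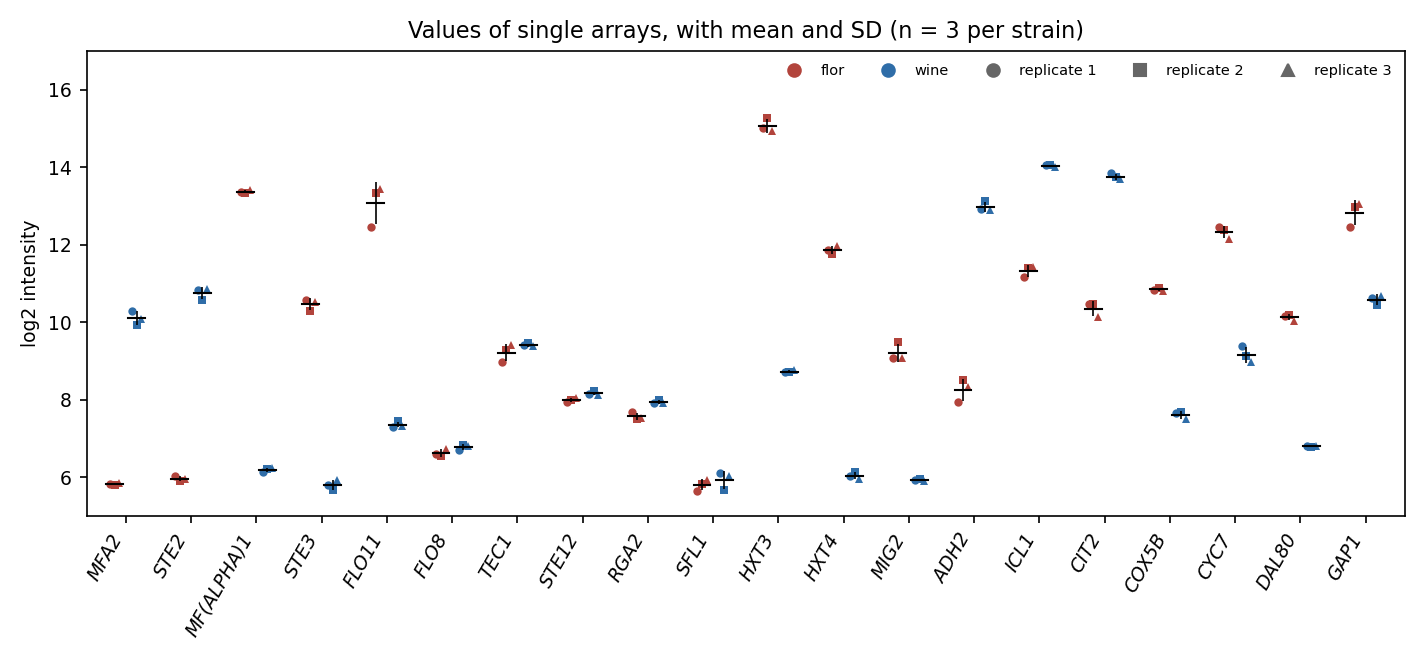
Log2 intensity on each of the 6 arrays (y axis) for 20 genes (x axis), flor strain in red and wine strain in blue, with the mean and SD of 3 arrays in black; marker shapes give the replicate number. FLO11 lies at 13.08 ± 0.54 in the flor strain and 7.36 ± 0.07 in the wine strain, while the values of TEC1, STE12, FLO8 and SFL1 lie close together.

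Of 24 genes of ethanol use, the glyoxylate cycle and gluconeogenesis, 22 were lower in the flor strain, FBP1 (0.74) was higher, and the regulator gene CAT8 (−0.04) did not pass. With single arrays left out, 19 to 21 were lower. CIT3 was 40.3-fold lower (35.5 to 45.8), ADH2 26.5-fold, the carnitine acetyltransferase gene YAT1 11.6-fold (9.15 to 14.6) and the peroxisomal citrate synthase gene CIT2 10.6-fold (8.95 to 12.5). CIT3 lay near the bottom of the measured range in the flor strain (5.85 ± 0.08), so its fold can understate the change. The list had a median of −1.47 (slides −1.49 and −1.46), with camera adjusted p = 4.6e-12 and adjusted p = 0.32 with an estimated correlation. Of 22 genes of hexose transport and sensing, 11 were higher, among them HXT3, HXT4 (56.9-fold, 49.6 to 65.2), HXT2 (28.2-fold, 22.9 to 34.8) and STD1 (6.97-fold), a regulator of glucose-induced transporter expression, and SNF3 (−0.28) and HXT17 (−0.33) were lower. SNF3 did not pass without wine replicate 2 or 3 (adjusted p = 0.11 and 0.10), nor HXT17 without wine replicate 2 (0.051). This list had a median of 0.50 (slides 0.46 and 0.67), with adjusted p = 7.8e-05 and adjusted p = 0.32 with an estimated correlation. Of 15 TCA cycle genes, 8 were lower, with FUM1 (−0.83), CIT1 (−0.80), LSC1 (−0.69) and SDH1 (−0.67) first, and SDH3 (0.31) was higher. SDH3 did not pass with slide as a block (adjusted p = 0.065) or without any one array other than flor replicate 2 (0.050 to 0.16), so 0 were then higher. The TCA median was −0.33 (slides −0.23 and −0.38), with adjusted p = 0.038, adjusted p = 0.47 with an estimated correlation, adjusted p = 0.080 without flor replicate 1, and adjusted p = 0.055 without the dimmest 25% of features.

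Of 34 genes of the respiratory chain and ATP synthase, 12 were higher, with COX7 (0.71) and ATP20 (0.63) first, and NDE1 (−1.19), QCR2 (−0.57) and NDI1 (−0.51) were lower (median 0.18, camera adjusted p = 0.064). The median of this list was 0.01 once the length trend was removed, and 6 were higher without wine replicate 3. QCR2 did not pass with slide as a block (adjusted p = 0.054) or without wine replicate 1, 2 or 3 (adjusted p = 0.076, 0.11 and 0.12). Of 7 genes of the mitochondrial genome, COX2 (2.30), COB (2.24), COX1 (1.02) and COX3 (0.44) were higher, and COX3 lost its call without wine replicate 3 (adjusted p = 0.064). The median of that list was 0.57, with 0.19 on slide 1 and 0.81 on slide 2 (adjusted p = 0.0081; adjusted p = 0.47 with an estimated correlation), and it was 0.33 without flor replicate 1 and 0.88 without flor replicate 3. In glycolysis and fermentation, 2 of 23 genes were higher, PDC6 (1.96) and HXK2 (1.77, 3.40-fold), and 5 lower, ENO1 (−0.89), TDH3 (−0.55), PYK2 (−0.43), ENO2 (−0.42) and TDH2 (−0.27). Without wine replicate 2 or 3, 2 were lower, and without flor replicate 3 or wine replicate 1, 3 were. PYK2 lost its call without flor replicate 3 or wine replicate 2 or 3 (adjusted p = 0.089, 0.086 and 0.12), ENO2 without wine replicate 1, 2 or 3 (0.10, 0.17 and 0.073) and TDH2 without any of these 4 arrays (0.057 to 0.10). Counts adjusted over the list alone were 2 higher and 2 lower, and the median was −0.01 and the mean 0.07 (adjusted p = 0.88, towards higher). Of 8 genes of maltose and sucrose use, the invertase gene SUC2 (2.33, 5.03-fold) was higher and MAL11 (−3.08), MAL33 (4.01-fold lower) and MAL13 (−1.28) were lower (median −0.03, adjusted p = 0.42; 2 higher without flor replicate 1). MAL genes of different loci share sequence and may not be separated. Of 20 anaerobic and hypoxic genes, COX5B (3.24, 9.46-fold), CYC7 (3.18, 9.04-fold), ANB1 (2.07) and AUS1 (0.91) led the 6 that were higher, and MGA2 (−0.87), SUT1 (−0.83), TIR3 (−0.62), HEM13 (−0.58) and ROX1 (−0.47) were lower. The median of that list was −0.06 and its mean 0.34 (adjusted p = 0.66, towards higher).

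Of 32 genes under nitrogen catabolite repression, 14 were higher, with the GABA permease UGA4 (4.01, 16.2-fold, 11.9 to 22.0), the repressor DAL80 (3.34), the allantoate permease DAL5 (2.81) and the general amino acid permease GAP1 (2.25) first, and 7 were lower. Adjusted over the list alone, 15 were higher and 7 lower. The list had a median of 0.16 and did not pass (camera adjusted p = 0.063), but it passed without flor replicate 1, wine replicate 2 or wine replicate 3 (adjusted p = 0.015, 0.043 and 0.049). Of 23 genes of thiamine, biotin and pyridoxine metabolism, 15 were higher and VHT1 (−1.15), a biotin transporter, was lower (2 lower without flor replicate 1). THI5 (2.47), THI12 (2.40), THI11 (2.40) and THI4 (2.01) were first, and THI5, THI11 and THI12 are near-identical copies. Probes of such copies may cross-hybridise, so they do not count as separate observations. The median of the list was 0.53 (slides 0.57 and 0.46), with adjusted p = 1e-05 and adjusted p = 0.32 with an estimated correlation. Of 31 genes of sulfur amino acid synthesis, 20 were lower, with the methionine permease MUP1 (−2.79, 6.93-fold), MET6 (−1.33), HOM3 (−1.04) and MMP1 (−0.93) first, and STR3 (0.83), MUP3 (0.70), MET32 (0.60), MET30 (0.40) and MET1 (0.27) were higher. MET30 lost its call without any one array other than flor replicate 1 (adjusted p = 0.050 to 0.087) and MET1 without flor replicate 3 or wine replicate 1 or 2 (0.064, 0.076 and 0.066), and without each of these 3 arrays 3 genes were higher. Adjusted over the list alone, 6 were higher and 20 lower, and the median was −0.46 (slides −0.35 and −0.51), with adjusted p = 0.0048 and adjusted p = 0.47 with an estimated correlation. Of 41 genes of amino acid synthesis under GCN4, 9 were higher and 16 lower, and with p adjusted over the list alone 10 and 17. ARG4 (−1.38), ARO1 (−1.08) and ARO2 (−1.02) were lower and LYS9 (1.37) was higher, with a median of −0.21 for the list (adjusted p = 0.091, and 0.032 without flor replicate 3). LYS9 varied widely among the flor arrays (12.80 ± 0.80) and did not pass on slide 2 alone (limma adjusted p = 0.13). Of 23 genes of purine and pyrimidine synthesis, 14 were higher, with ADE17 (1.67), MTD1 (1.51) and ADE1 (1.11) first, and 6 were lower, with URA2 (−1.21) first (3 lower without wine replicate 3). The median was 0.40 (slides 0.48 and 0.34), with adjusted p = 0.021 and adjusted p = 0.47 with an estimated correlation.

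Of 24 ergosterol synthesis genes, 13 were higher, with ERG28 (1.11), ERG25 (0.94) and ERG5 (0.87) first, and ERG6 (−1.02), ERG24 (−0.71) and HMG2 (−0.32) were lower. HMG2 did not pass without flor replicate 3 or wine replicate 2 or 3 (adjusted p = 0.072, 0.15 and 0.091). With p adjusted over the list alone, 14 were higher and 5 lower, and the median was 0.31 (slides 0.33 and 0.28), with camera adjusted p = 0.015 and adjusted p = 0.46 with an estimated correlation. Of 17 genes of fatty acid and lipid synthesis, 9 were lower, with the acyl-CoA synthetase FAA4 (−1.81, 3.51-fold), INO1 (−1.19), FAS1 (−1.04) and ACC1 (−0.93) first, and ELO1 (0.81) and INO4 (0.35) were higher. INO4 did not pass without wine replicate 1 or 2 (adjusted p = 0.082 and 0.079), which left 1 higher, and 4 were higher without flor replicate 1. With p adjusted over the list alone, 4 were higher and 9 lower, and the median was −0.47 (adjusted p = 0.078, and 0.049 without flor replicate 3). All 9 measured PAU genes, a family of near-identical cell wall mannoproteins, were higher, from PAU23 (0.51) to PAU3 (1.34), with PAU7 at 1.16, PAU1 at 0.91 and PAU24 at 0.88. Their median was 0.86 (slides 0.68 and 0.99), with adjusted p = 0.00035 and adjusted p = 0.47 with an estimated correlation, and 7 of the 9 passed once the length trend was removed (median 0.67, adjusted p = 0.017). PAU23 did not pass without flor replicate 3 (adjusted p = 0.052), and 8 of the 9 passed without wine replicate 3. The members of this family were measured by probes that may cross-hybridise, so they do not count as separate observations.

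Of 28 genes of iron and copper uptake, 12 were lower, with the copper transporters CTR3 (−2.48, 5.59-fold) and CTR1 (3.99-fold lower) and the siderophore transporters ARN1 (−2.11) and SIT1 (−2.07) first, and 6 were higher. Adjusted over the list alone, 7 were higher and 12 lower (median −0.08, camera adjusted p = 0.078). Without the dimmest 25% of features the list passed, with a median of −0.34 (adjusted p = 0.025). Of 9 genes of zinc homeostasis, ZRT1 (1.60, 3.04-fold), ZPS1 (0.92), ZRT2 (0.74) and ZAP1 (0.32) were higher and COT1 (−0.71) and ZRC1 (−0.25) lower (median 0.18, adjusted p = 0.14). ZRC1 did not pass with slide as a block (adjusted p = 0.052) or without flor replicate 2 or wine replicate 1, 2 or 3 (0.093, 0.063, 0.075 and 0.14), which left 1 lower. Of 18 genes of the phosphate regulon, 7 were higher, with SPL2 (2.68, 6.40-fold), the phosphate transporter PHO84 (2.29), PHM6 (1.95) and PHO5 (0.54) first, and PHO11 (−0.46), PHO89 (−0.31) and PHM8 (−0.30) were lower. PHO89 lost its call without any one array other than flor replicate 1 (adjusted p = 0.055 to 0.097) and PHM8 without wine replicate 1 (0.050), which left 1 lower. With p adjusted over the list alone, 8 were higher and 4 lower. The list had a median of 0.25 and did not pass (adjusted p = 0.063), but it passed without flor replicate 1 or wine replicate 3 (adjusted p = 0.015 and 0.049).

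Of 28 genes of general stress, trehalose and glycogen, 15 were lower in the flor strain, with ALD3 (−1.64), the catalase CTT1 (−1.58) and the glycogen synthase GSY2 (−1.44) first, and SIP18 (1.64), GRE1 (1.14), ALD2 (1.10) and SSA3 (0.75) were higher. The list had a median of −0.32 (camera adjusted p = 0.064), and it passed without flor replicate 2 or wine replicate 1 (adjusted p = 0.026 and 0.035). Of 15 heat shock chaperones, MDJ1 (−0.68), HSP60 (−0.58), SSC1 (−0.52) and SIS1 (−0.50) were lower and none was higher (median −0.38, adjusted p = 0.11). Without flor replicate 1 the median was −0.12 (adjusted p = 0.32), and without flor replicate 2 it was −0.53 (0.026). Without flor replicate 2, 7 chaperones were lower, and without wine replicate 2, 2 were. HSP60 lost its call without wine replicate 1 or 2 (adjusted p = 0.058 and 0.071) and SSC1 without wine replicate 2 or 3 (adjusted p = 0.10 and 0.068). Of 23 genes of oxidative and sulfite stress, 7 were lower, with OYE3 (−1.27), GLR1 (−1.05) and OYE2 (−0.68) first, and HYR1 (0.64), GRX1 (0.51), ATR1 (0.39) and the sulfite pump SSU1 (0.29) were higher. SSU1 did not pass without flor replicate 3 or wine replicate 2 or 3 (adjusted p = 0.051, 0.059 and 0.062). The median of that list was 0.02 and its mean −0.08 (adjusted p = 0.88, towards lower).

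Of 66 ribosome biogenesis genes, 10 were higher, with CIC1 (1.13) first, and 20 lower, with RRP12 (−0.76), NOP1 (−0.73) and NOP58 (−0.70) first (median −0.12, camera adjusted p = 0.42). Lower genes numbered 12 without flor replicate 3, 9 without wine replicate 1 and 10 without wine replicate 3, and 6 were higher without wine replicate 1 or 2. Of 135 genes in the cytosolic ribosomal protein list, RPL34B (1.07) and RPS14A (0.37) were higher and 22 were lower, with RPL18B (−1.09), RPS28B (−0.97) and RPS11A (−0.85) first, and with p adjusted over the list alone 1 was higher and 13 lower. RPS14A did not pass with slide as a block (adjusted p = 0.062) or without flor replicate 3 or wine replicate 2 or 3 (0.072, 0.12 and 0.15). Without flor replicate 2, 12 were higher, and without wine replicate 1 or 3, 12 and 13 were lower. The list was drawn by name pattern and also holds RPP1, a subunit of RNase P. Its median was −0.04 (adjusted p = 0.42), but without flor replicate 1 it was −0.16, with 50 members lower (adjusted p = 0.0022). Of 20 G2/M and M/G1 genes, 10 were lower, with DSE2, the chitinase gene CTS1 (−1.50) and EGT2 (−1.06) first, and ALK1 (1.30), CLB2 (0.86), CLB1 (0.41) and HST3 (0.32) were higher. CLB1 did not pass without flor replicate 3 or wine replicate 1 or 2 (adjusted p = 0.10, 0.12 and 0.093), nor HST3 without wine replicate 2 (0.056), which left 2 higher. Adjusted over the list alone, 4 were higher and 11 lower, and the median was −0.27 (slides −0.25 and −0.31), with adjusted p = 0.047 and adjusted p = 0.47 with an estimated correlation. This call was lost without wine replicate 3 (adjusted p = 0.066), with slide as a block (0.052), with each array centred on its median (0.051), without the dimmest 25% of features (0.059) and once the length trend was removed (0.18). Of 15 G1/S genes, POL30 (0.82) and MNN1 (0.47) were higher and CLN1 (−0.87), CLN2 (−0.72) and RNR1 (−0.46) lower (median 0.14, mean 0.00, adjusted p = 0.88; 6 higher without flor replicate 1). Of 10 core histone genes, HHT1 (0.54) and HHF1 (0.35) were higher and HTA1 (−0.33) lower, and with p adjusted over the list alone 2 were higher and 0 lower (median 0.07, adjusted p = 0.48). HHF1 lost its call without wine replicate 1 (adjusted p = 0.077) and HTA1 without any one array other than flor replicate 1 (adjusted p = 0.055 to 0.14), whose omission left 0 lower, while without flor replicate 1 there were 2.

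Of 10 common laboratory marker genes, ADE2 (0.45) and URA3 (0.40) were higher and MET17 (−0.79) lower (median 0.03, camera adjusted p = 0.79), so that none of the markers was near background in 1 strain only. ADE2 did not pass without wine replicate 2 (adjusted p = 0.052), nor URA3 without flor replicate 3, wine replicate 1 or wine replicate 2 (adjusted p = 0.062, 0.066 and 0.053). Of 13 genes present in the S288C reference and missing from many other strains, SEO1 (5.15), AQY2 (1.81), YRF1-1 (1.30) and ENA2 (0.90) were higher in the flor strain and none was lower (median 0.12, slides 0.06 and 0.05, adjusted p = 0.023; adjusted p = 0.32 with an estimated correlation). The median was 0.05 without flor replicate 1 or 3 (adjusted p = 0.015 and 0.031). YRF1-1 and ENA2 belong to families of near-identical copies.

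**Figure D3:**
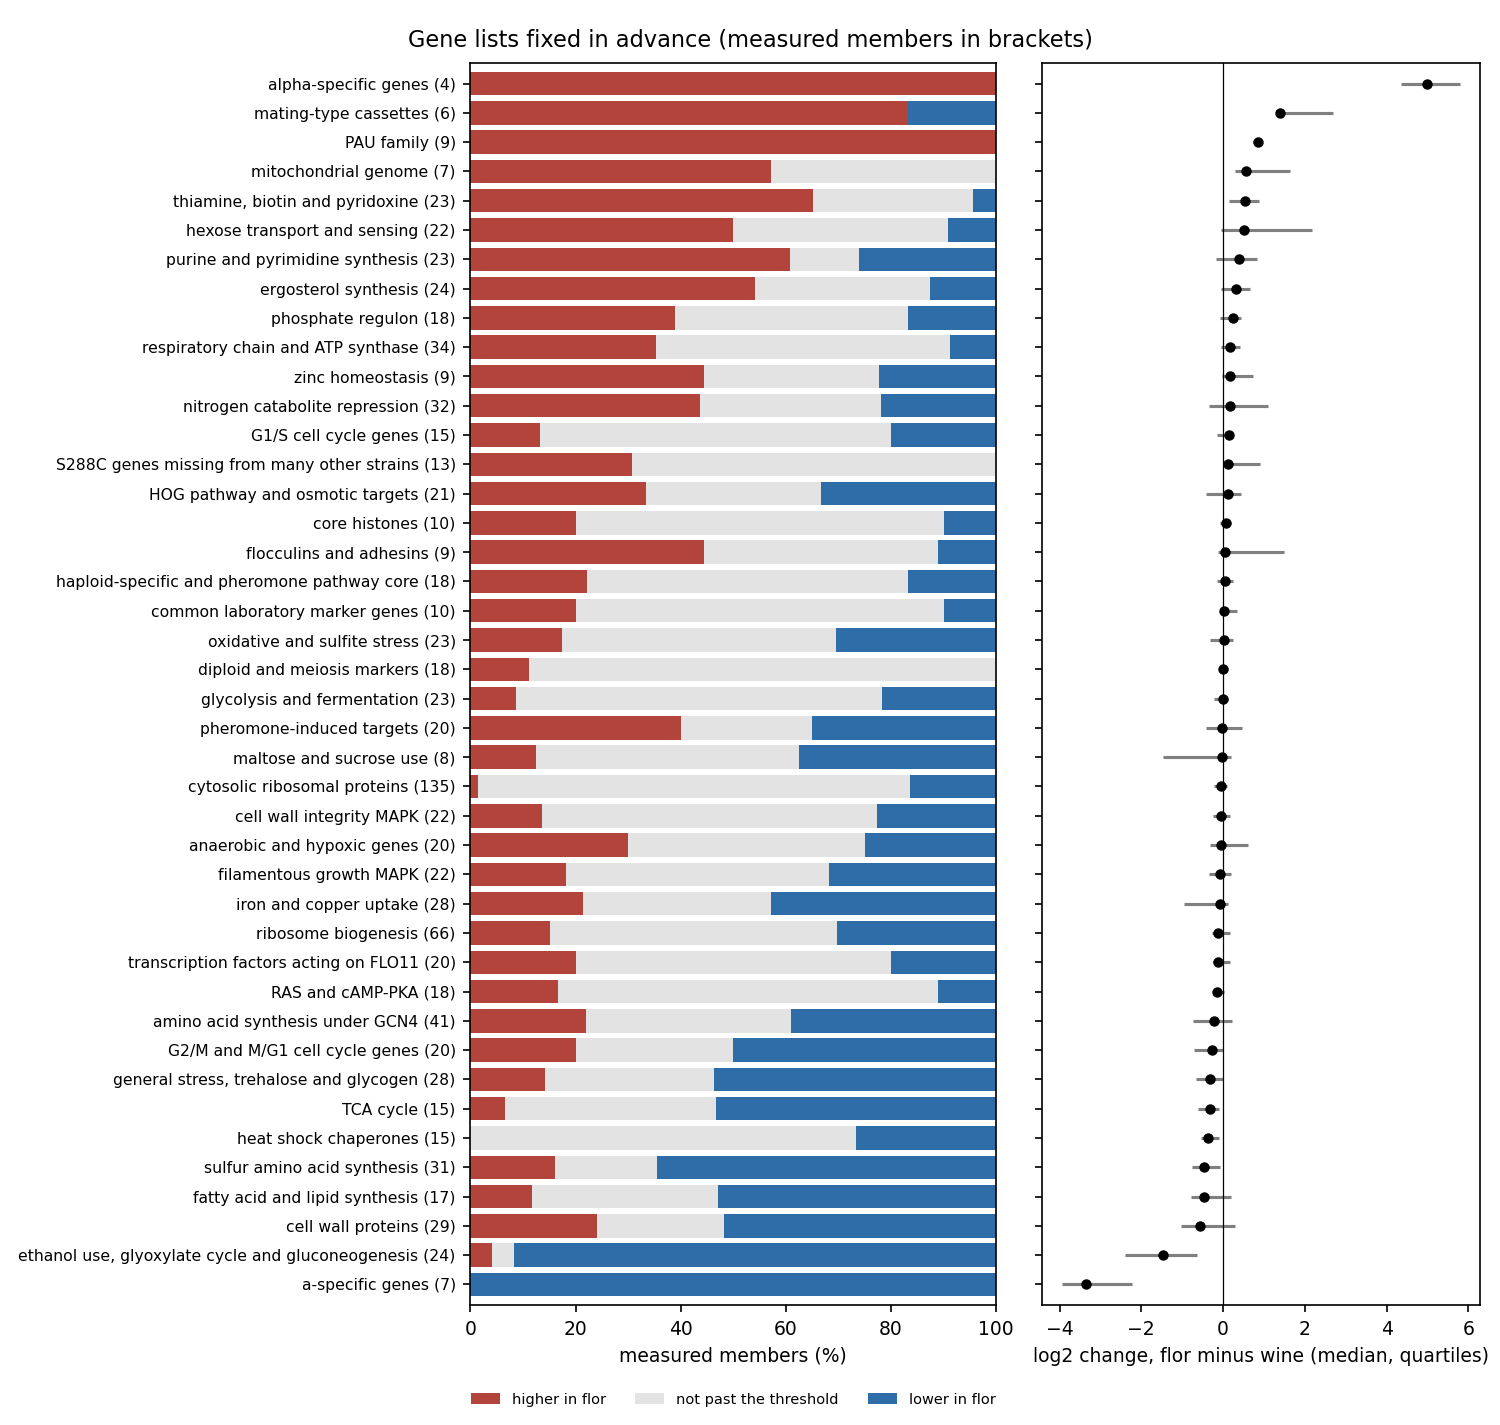
Left, share of the measured members of each of the 42 gene lists that were higher (red), lower (blue) or not past the threshold (grey) in the flor strain; right, median log2 change, flor minus wine, with the quartiles as a line. The medians run from −3.36 for the a-specific genes to 4.99 for the alpha-specific genes.

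In all, 14 of the 42 lists passed with camera's preset correlation of 0.01 and 0 passed with an estimated correlation. By fry, 27 lists moved on balance one way and 41 held changes in either direction. In 29 lists the counts adjusted over the list alone were those given for all genes, and the 13 with other counts are given above. Log2 changes fell with coding length across 4035 genes (Spearman correlation −0.23, and −0.13 without flor replicate 1, where genes are not independent replicates). Among the arrays, the deviation of flor replicate 1 from its strain mean correlated with coding length at −0.45, and that of wine replicate 1 at −0.35. Flor replicates 2 and 3 stood at 0.34 and 0.42, and wine replicates 2 and 3 at 0.21 and 0.16. Deviations from a shared mean are tied to each other, so these signs are not independent. Without flor replicate 1, 3279 features differed, the adhesin, phosphate, nitrogen catabolite repression and ribosomal protein lists passed, and the TCA list did not. Removal of a smooth length trend from each array, an alternative chosen after seeing the data, left 2016 of 4035 genes differing against 1910 before it. Of these, 947 against 803 were higher and 1069 against 1107 lower. The trend was fitted to deviations from the mean over both strains, so any strain difference that follows length was removed with it. Calls lost or gained under this removal therefore do not separate an array effect from a strain difference. With the trend removed, the adhesin, phosphate and nitrogen catabolite repression lists passed (adjusted p = 0.017 each), as did the ribosomal protein list (0.031), while SOK2 and HHF1 did not pass (0.22 and 0.18).

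No whole chromosome stood apart. Median log2 changes per chromosome ran from −0.16 for III to −0.02 for VIII over 4035 genes, whereas a doubled chromosome in a haploid would give about 1. By camera, 0 of 16 chromosomes passed with the preset or an estimated correlation, and 0 had an unadjusted p under 0.05. Genes at chromosome ends differed more often than others. Among the outermost 15 protein-coding genes of each end in the R64 reference order, 154 of 245 measured genes (62.9%) passed the test against 1746 of 3790 others (46.1%), an odds ratio of 1.98 (1.51 to 2.62, Fisher's exact test, two-sided, p = 4.3e-07). Changes of at least 1 on the log2 scale made up 24.1% of the end genes and 5.6% of the others. Only 245 of the 480 annotated end genes were measured under a name. Fisher's test takes genes as independent, and members of near-identical families were counted one by one, so its interval and p can be too narrow.

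Of the 2166 unnamed probes, 471 were higher and 364 lower in the flor strain, and 4 of the 40 largest changes (20 in each direction) were of this kind, each of them an increase. The largest increases among unnamed probes were 25.7-fold for A_06_P1766 (22.3 to 29.5) and 25.4-fold for A_06_P1982, which are among these 4. The largest decreases among unnamed probes, which are not, were 5.36-fold for A_06_P6187 (4.78 to 6.01) and 4.78-fold for A_06_P4600. No gene is assigned to these probes here.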

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

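The count of 2746 differing features stayed within 2040 and 3279 when single arrays were left out, at 2746 to 2756 under the other normalizations and scalings, at 2578 with slide as a block and at 3770 with array weights, whose fit did not fully converge. It fell with fewer features, on slide 2 alone or with a stricter threshold, which these settings impose by construction. Without the dimmest 50% of features 1543 differed (705 higher, 838 lower), on slide 2 alone 1424 (701 and 723), at an adjusted p under 0.01 1761 (841 and 920), and against a log2 change of 0.5 519 (297 and 222). With the unnamed probes left out, 811 genes were higher. Of the genes with a length, chosen as a set after seeing the data, 803 were higher, and with the length trend removed 256 changed by at least 1 on the log2 scale, where fewer features were tested. The share of calls that were higher in the flor strain, 46.5%, lay between 42.0% and 49.2% except against a change of 0.5 (57.2%), and the scalings gave 45% to 46.5%. The count of lists, 14, was 0 with an estimated correlation between genes in place of the preset. It was 27 by fry, which asks another question, and 15 to 17 with single arrays left out under the preset. The fall to 0 is not due to correlation alone. The list of S288C genes missing from many strains had an estimated correlation of −0.048, under the preset, yet its camera p rose from 0.0067 to 0.045. None of the 14 calls was kept by that alternative, but its result does not show them false. With replicate number as a block, 2973 features differed (1393 higher, 1580 lower) and 15 lists passed. Deviations of same-numbered arrays correlated at 0.37, 0.23 and 0.05, and those of other pairs at −0.33 to 0.19. Flor replicate 3 correlated best with wine replicate 2 (0.19), with which it shared slide 1. Whether arrays of the same number form pairs is therefore not settled. The block changed the call of no gene named by the rule, and the general stress list passed with the block (camera adjusted p = 0.033). HTA1 did not pass with an intensity trend and robust eBayes (adjusted p = 0.057). The odds ratio for chromosome ends lay between 1.47 (outermost 25 genes) and 2.56, and 0 chromosomes passed in any setting. Of 173 genes named by the rule, 168 passed, 117 of these in every alternative, and 0 reversed; all 51 that lost the call in some setting lost it against a change of 0.5, 18 on slide 2 alone and 12 at an adjusted p under 0.01. The rules for several probes of a gene affect FDH2 alone and test little. The other normalizations and scalings test little too, because the deposited columns already had nearly one distribution. Signal over background is unknown for single probes, which limits the reading of levels near 6.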

Other observations

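The genes in this paragraph and the next were chosen after their values were seen, and each change has n = 3 arrays per strain and a limma adjusted p. Among permease genes, BAP3 (−4.03 ± 0.08, SE), BAP2 (−3.38 ± 0.12), TAT1 (−2.11), TAT2 (−1.91), AGP1 (−1.58), GNP1 (−1.02) and DIP5 (−0.31, adjusted p = 0.035), which carry amino acids, were lower in the flor strain, and no list of permeases was tested. The general permease GAP1 (2.25 ± 0.15) and the peptide transporter PTR2 (2.05 ± 0.13) were higher, but DIP5 did not pass with slide as a block (adjusted p = 0.056) or without flor replicate 3 or any wine array (0.087 to 0.10), and the arginine permease CAN1 was not called (−0.05, adjusted p = 0.76). CIT3, PDH1 and ICL2, which take part in propionate breakdown, were lower by −5.33, −4.01 and −2.08 (adjusted p = 2.6e-07 for ICL2), and no list of such genes was tested. Their intensities in the flor strain were 5.85 ± 0.08, 7.69 ± 0.03 and 8.60 ± 0.10 (SD).

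In 3 pairs of isoform genes, picked from an anaerobic and hypoxic list that did not pass (camera adjusted p = 0.66, 6 genes higher and 5 lower), the member known for low-oxygen use was higher while the aerobic member changed less. COX5B rose by 3.24 against 0.37 for COX5A, CYC7 by 3.18 against 0.39 for CYC1, and ANB1 by 2.07, while HYP2 did not pass (−0.22, adjusted p = 0.10). COX5A lost its call without flor replicate 3 or wine replicate 3 (adjusted p = 0.056 and 0.068) and CYC1 without wine replicate 2 or 3 (0.053 each). Other genes tied to low oxygen went the other way, with SUT1 at −0.83, HEM13 at −0.58 and HMG2 at −0.32. HMG2 did not pass without flor replicate 3 or wine replicate 2 or 3 (adjusted p = 0.072, 0.15 and 0.091). Of genes with a role in daughter-cell separation, for which no list was tested, the lower ones were DSE2 (−2.05), DSE4 (−2.01), CTS1 (−1.50), EGT2 (−1.06), DSE1 (−1.03) and SCW11 (−0.96), while DSE3 (−0.02) was not called and AMN1, a repressor of that programme, was slightly higher (0.39, adjusted p = 0.0047). The glucose repressor gene MIG2 was 9.72-fold higher (8.09 to 11.7). Its level in the wine strain, 5.93 ± 0.03 (SD), was near the bottom of the measured range, so this fold can understate the change.

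The tests on growth, glucose, chromosome ends (at each limit), coding length and slide, and the other splits for the counts of differing features and of large changes, were chosen after the results were seen, while those for the lists and chromosomes were written before. The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 2746 differing features and the highest other split 0, so 1 of 10 was as large, and likewise 399 large changes against 0 (1 of 10). For the lists, 2 of 10 splits gave as many, with 14 in the real split and 14 in the one that joins flor replicate 1 with wine replicates 2 and 3. Each of the 9 other splits puts arrays of both strains on each side. Part of the strain difference then stays between the sides, and the rest widens the spread within them, which lowers the counts of features. The 0 of the other splits therefore says little about chance. For chromosomes, 10 of 10 splits gave 0.

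Of 22 hexose transport and sensing genes, 11 were higher and 2 lower in the flor strain, and of 24 ethanol-use genes, 22 were lower and 1 higher, although both strains were collected at the same optical density; neither list passed with an estimated correlation (adjusted p = 0.32 each). Slower or nearly arrested wine cultures would lower their ribosome biogenesis genes, and the median of these was −0.12 (quartiles −0.27 and 0.16; −0.06 without flor replicate 3), which goes the other way, but 15 of 28 stress and reserve genes were higher in the wine strain (median −0.32, camera adjusted p = 0.064, and 0.026 without flor replicate 2 or 0.035 without wine replicate 1), as such cultures would give, so that explanation stays open. Whether glucose was used up in the wine cultures only was not settled either. Of 12 genes raised by low or absent glucose, 4 were lower and 6 higher in the flor strain. PCK1, one of the lower, did not pass without any one array (limma adjusted p = 0.053 to 0.16). But 9 of the 12 belong to the hexose and ethanol-use lists whose change is in question. The 12 also mix genes raised by low glucose with genes raised by its absence, which need not move together, so the count decides nothing. Residual sugar at collection may differ and cannot be told apart from a difference between the strains, which was not tested and goes together with mating type.

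Some genes had a mean log2 intensity under 6 in one strain and at least 2 units more in the other. Outside the mating genes these were 8 named genes, SEO1, MIG2 and DOG2 (which has a near-identical copy) lower in the wine strain and MAL11, AYT1, FDH1, FDH2 and CIT3 lower in the flor strain. SEO1, MAL11, AYT1 and FDH1 lie at chromosome ends, 4 of 240 end genes against 4 of 3778 others (odds ratio 16, 2.95 to 86.1, Fisher's exact test p = 0.00072), while a limit of 6.5, which adds genes such as SOR1, HXT4, HXT2 and PRM2, gave 6 against 9 (odds ratio 10.7, 3.11 to 34, p = 0.00014) and a limit of 7 gave 7 against 17 (6.64, 2.3 to 17, p = 0.00036). FDH2, annotated as a pseudogene, was not counted as an end gene. Absent or divergent genes at chromosome ends are a candidate explanation for that part, but silencing or regulation near ends would give the same excess, and no genome sequence of either strain was used here.

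Flor replicate 1 stood apart from the other flor arrays. If the slide were the reason, it would lie closer to replicate 2, on its own slide, than to replicate 3, but its correlations were 0.9877 and 0.9903. Its deviation from the flor mean fell with coding length across genes (Spearman correlation −0.45), with medians of 0.16 for the shortest 25% of genes and −0.08 for the longest 25%. A difference in RNA or label quality linked to transcript length may explain this. Wine replicate 1 leaned the same way (−0.35) but by less, with medians of 0.04 for the shortest 25% of genes and −0.03 for the longest 25%. A feature shared by the cultures numbered 1 stays open too. Without flor replicate 1, 3279 features differed, 2709 of them among the 2746 found with all arrays. The TCA list then lost its call (camera adjusted p = 0.080) and the ribosomal protein list passed (0.0022).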
